A study of Mus musculus with 4 samples.

How the data were processed

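Single-cell gene expression was measured in macrophages sorted from the perigonadal white fat of mice, as live cells positive for CD45, CD11b and CD64 and negative for a lineage stain, per the labels. The 4 libraries were made with the 10x Genomics Chromium 3′ workflow and run on an Illumina NovaSeq, and each stands for 1 group: control (WT) or BLIMP1 conditional knockout (CKO) mice, on a high-fat diet (HFD) or a normal diet. Library and group are the same thing in this design, so 1 library per group is all that any comparison rests on, and nothing here separates a group from the preparation of its library. The number of animals behind a library, the driver of the knockout and the deleted exons are not given in the sources used here.

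The values are raw UMI counts per gene and cell barcode, which Cell Ranger 7.0.0 wrote per the file headers. The genome build, GRCm38, comes from the submitters' processing entries. Whether intron reads were counted is not given in the sources used here. Each deposited count matrix holds called cells, with a lowest total of 500 to 509 UMIs per cell, and the same 32285 genes. Of the gene identifiers, 32235 (99.8%) were found in the GENCODE M21 annotation of GRCm38, from which gene positions and spans were taken. The 40 symbols that name more than 1 gene were kept apart by identifier.

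Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% of UMIs from mitochondrial genes. Doublets were called with Scrublet as implemented in scanpy 1.11.5, in each library by itself. Its automatic threshold called 1 cell in WT HFD, 0 in CKO HFD, 2 in WT normal diet and 4 in CKO normal diet. For a library of over 5000 cells with under 0.5% called, a rule fixed in advance removes the top 0.8% of scores per 1000 cells. That rule applied to CKO HFD alone and removed 610 cells (6.99%), so that the 4 libraries were not treated alike. Removing top scores by the same rule in all 4 libraries was tried as an alternative, in which the share removed still grows with the number of cells.

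All kept cells were clustered together: counts per 10000 UMIs, log1p, 2000 variable genes chosen within library, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9). No integration was used, since it would remove group differences with library differences. Cell classes were rebuilt from the 22 clusters, as the authors' labels of single cells were not analysed here. A cluster took the name of the class, out of 22 marker lists fixed beforehand, with the most markers among its 20 leading genes, if at least 3 markers were there and no other class had as many. Leading genes had at least 100 CPM in the cluster and the highest log2 fold over the other cells (pseudocount 20), and a marker counted at a log2 fold of at least 1. The numbers in this naming rule were chosen after the clusters had been seen. Clusters named for dendritic cells, lymphoid cells and fibroblasts were left out, and the remaining cells, unnamed clusters included, are called phagocytes.

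UMIs were summed over the phagocytes of each library and scaled to a total of 1000000 UMIs (CPM). Levels carry exact Poisson intervals, ratios exact conditional binomial (Clopper-Pearson) intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and for counting error only. No test across libraries was run and no p-value is given, since single cells of 1 library are not replicates. The 4 comparisons were CKO over WT under each diet, and HFD over normal diet in each genotype. Gene ratios were also taken within classes of at least 100 cells in both libraries.

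For each of 27 gene lists the median log2 ratio of (CPM + 1) was taken over the members with at least 10 CPM in 1 of the 2 libraries, with an interval from 1000 Poisson redraws. The median was placed by percentile among 10000 random lists of the same size matched on mean expression (20 bins). The random lists were not matched on gene span, so a trend of the ratios over gene length can move a percentile. The lists were lipid-associated, resident, classical monocyte, MHC class II, MHC class I, interferon, inflammatory, chemokines, lysosome, lipid handling, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, glycolysis, hypoxia, iron, complement, phagocytic receptors, alternative activation, matrix remodelling, BLIMP1 related, unfolded protein, dissociation response, cell division, ribosome, free RNA of other cells, and sex. Members over 1.5 times higher or lower are counted by size, not by test.

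Named genes were chosen by rule: for each comparison the 10 highest and the 10 lowest ratios of (CPM + 10) among genes with at least 50 CPM and 100 UMIs in the higher library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, predicted genes, the sex list and the list of free RNA were left out. The rule adds Prdm1 and, from each list, the 3 members with the highest mean CPM and the member of at least 50 CPM farthest out in each direction. Shares of cells with a UMI were taken after each phagocyte was thinned to 2000 UMIs. These lists, thresholds and comparisons were fixed before the data were examined.

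The alternatives chosen in advance were TMM scaling (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial and ribosomal protein genes, no minimum CPM or 50 CPM, a pseudocount of 10, cells weighted equally, a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), doublet calls kept, all kept cells, equal class weights, thinned cells, Leiden resolutions 0.5 and 2, clustering of thinned cells, and phagocytes as the denominator of shares. They were fixed for the lipid-associated, resident and MHC class II lists in CKO over WT under both diets and HFD over normal diet in WT, for the lipid-associated-like shares and for the named genes. The same settings for these lists in HFD over normal diet in CKO and for the resident-like shares were chosen after seeing the data. Equal class weights, or classes weighted equally, used the 6 phagocyte classes with at least 20 cells in every library. A class took the same weight in every library, in proportion to its mean share of phagocytes over the 4 libraries. Large classes therefore counted more than small ones. The procedure was tested on simulated data, in which 200 genes were given a known change between redrawn libraries: 97%, 97%, 93% and 94% of the changed genes' intervals held the true ratio in the 4 comparisons, and 20 of 20 named genes were ones with a changed level. The simulated counts were independent Poisson draws, which the intervals assume, so this does not test genes whose UMIs lie in a few cells. A list given no shift lay at percentiles 96.6, 68.8, 10.7 and 58.2, so that a percentile of this size does not by itself mark a list as changed. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.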

Results

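The series asks how macrophages of visceral fat differ in subsets and function when BLIMP1, a transcriptional repressor encoded by Prdm1, is conditionally deleted, under a normal diet and a high-fat diet. It holds 4 libraries, 1 for each of WT HFD, CKO HFD, WT normal diet and CKO normal diet, and no replicates. The deposited matrices held 5054, 8749, 3737 and 4327 cells in that order, with 74879066, 42566954, 21829741 and 24543868 UMIs. After filtering, 4649, 8121, 3703 and 4298 cells were kept, with median depths of 14490, 3738, 4086 and 3938 UMIs and 3541, 1424, 1830 and 1808 genes per cell. In WT HFD 400 cells were over the mitochondrial limit, against 7, 23 and 23 in the others. Phagocytes made up 96.6%, 97.3%, 90.9% and 92.6% of the kept cells, and their pooled profiles held 72392103, 35448887, 19939334 and 22667292 UMIs. All intervals given are 95% intervals for counting error only and say nothing about differences between animals or preparations.

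Prdm1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501, minus strand, GRCm38) was not lower in the CKO libraries. Over all kept cells it stood at 21.8 CPM (20.8 to 22.9) in WT HFD, 23.3 CPM (21.8 to 24.9) in CKO HFD, 22.8 CPM (20.9 to 24.9) in WT normal diet and 28.3 CPM (26.3 to 30.5) in CKO normal diet. Among phagocytes the ratio CKO over WT was 1.06 (0.972 to 1.15) under HFD and 1.21 (1.07 to 1.37) under normal diet. After thinning to 2000 UMIs, 4.10%, 4.44%, 5.16% and 6.01% of phagocytes had a Prdm1 UMI, and without thinning 21.9%, 8.53%, 9.83% and 11.9%. The thinned shares rest on 4442, 6876, 2730 and 3197 cells, as 47, 1023, 637 and 783 cells were too shallow. In fibroblast-like cells, taken as the background of free RNA, 0 of 50, 0 of 58, 0 of 4 and 0 of 6 thinned cells had one. A 3′ tag outside the deleted part of the gene checks nothing about the deletion.

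Lipid-associated-like macrophages, the Trem2-positive cells of obese fat, were more frequent under HFD and less frequent in CKO. They made up 24.4% (23.1 to 25.6) of kept cells in WT HFD, 14.6% (13.8 to 15.4) in CKO HFD, 2.84% (2.33 to 3.42) in WT normal diet and 1.42% (1.09 to 1.82) in CKO normal diet. The share in CKO was 0.599 times (0.552 to 0.651) that in WT under HFD and 0.501 times (0.359 to 0.693) under normal diet. HFD over normal diet gave 8.59 times (7.03 to 10.6) in WT and 10.3 times (7.95 to 13.5) in CKO. The size of these diet ratios, and which genotype had the larger, depended on the clustering: 10.03 in WT and 2.47 in CKO at Leiden resolution 0.5, 10.03 and 8.53 at resolution 2, and 5.02 and 3.71 with centring within libraries. The class was held by different clusters: in WT HFD by one led by Gpnmb, Atp6v0d2, Ctsl and Trem2 (1092 cells), in CKO HFD by one led by Arg1, Timp1, Hilpda and Ccl24 (1085 cells). At Leiden resolution 0.5 the CKO HFD share was 3.04%.

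Resident-like cells, named from markers such as Lyve1, Folr2 and Cd163, made up 26.0% of WT HFD, 51.6% of CKO HFD, 33.9% of WT normal diet and 41.5% of CKO normal diet. The clusters behind them were again separate, with 1146 cells of WT HFD in one, 2974 and 1054 cells of CKO HFD in another pair, and 970 and 1319 cells of the normal-diet libraries in a shared one. The larger CKO HFD cluster was led by Ccl12, Mt1, Ccl7 and Ccl2 and had Lyve1 at 100.07 CPM, against 212 CPM in the WT HFD cluster, 433 and 569 CPM in the shared cluster and the smaller CKO HFD cluster, and 141 CPM in an unnamed one. Its Folr2, at 517 CPM, was not below the 481 CPM of the WT HFD cluster. Without that cluster the share in CKO HFD was 14.99%, 0.589 times that in WT HFD and 0.363 times that in CKO normal diet, both in the opposite order. The HFD shares also depended on the clustering: WT HFD held 1.16% with the class markers left out of the clustering genes, and centring within libraries gave 13.1% in WT HFD and 12.02% in CKO HFD, the opposite order. No difference in resident-like cells under HFD is therefore claimed. Under normal diet the share in CKO was 1.16 to 1.33 times that in WT under every clustering and filter run. Classical monocyte-like cells, led by interferon-induced genes such as Cxcl9, Isg15 and Rsad2, were 4.30 times (3.02 to 6.31) as frequent in CKO HFD (3.24%) as in WT HFD (0.753%), and 1.16% and 1.12% under normal diet. Cluster 14 alone made up this class, with Ly6c2 at 212 CPM. Its complement gene C1qa stood at 2026 CPM, against 70.1 CPM in the larger non-classical monocyte-like cluster. Its Ccr2, at 773 CPM, was below the 1333 and 1160 CPM of the largest unnamed clusters. The class may thus hold macrophages, and no rise of monocytes is claimed. Dividing cells made up 11.2%, 7.04%, 4.64% and 6.70% of the WT HFD, CKO HFD, WT normal diet and CKO normal diet libraries.

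Non-classical monocyte-like cells made up 13.3% and 9.61% of the WT and CKO normal-diet libraries and 0.602% and 0.542% of the HFD libraries. Cells like type 2 conventional dendritic cells made up 5.51% and 5.03% under normal diet, and 0.538% and 0.086% under HFD. The cavity-like class, with markers of serous cavity macrophages, made up 0.891% and 0.861% under normal diet, and 0 HFD cells, which allows up to 0.079% in WT and 0.045% in CKO. Fibroblast-like cells made up 1.51%, 0.973%, 0.108% and 0.186% of WT HFD, CKO HFD, WT normal diet and CKO normal diet, and unnamed clusters 33.6%, 20.2%, 34.2% and 31.4%. The largest unnamed clusters were led by Tnip3, Ccr2 and Ciita in WT HFD (1347 cells) and by Chil3, S100a6 and Ifitm3 in CKO HFD (1482 cells). Under normal diet they were clusters 6 (468 WT and 545 CKO cells) and 10 (506 and 517 cells), both led by Lyz1. Cluster 6 had C1qa at 215 CPM and Fcgr1, the gene of CD64, at 3.10 CPM. The type 2 dendritic-like cluster had Fcgr1 at 4.23 CPM. Cluster 10 had C1qa at 1278 CPM and Fcgr1 at 27.8 CPM. Whether the cells of cluster 6 are macrophages is not settled here, and they count as phagocytes in every comparison. The sort for CD64, a receptor that monocytes and dendritic cells carry at lower levels than macrophages, and for CD45, which fibroblasts lack, can set the shares of these classes.

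**Figure D1:**
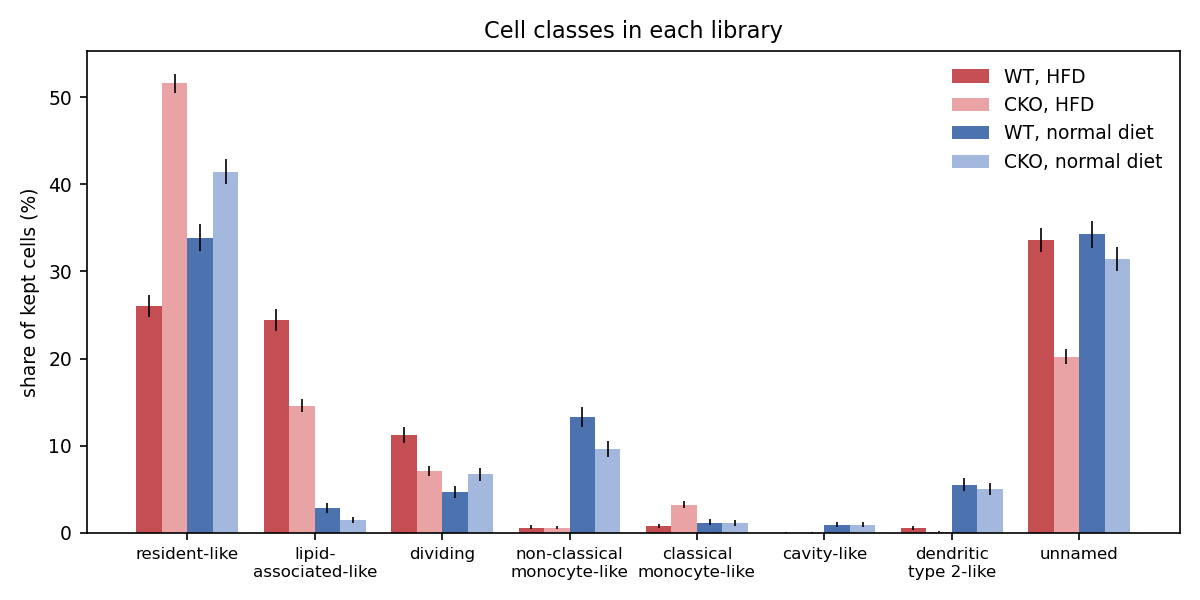
Share of kept cells (%, vertical axis) in each rebuilt class for the 4 libraries, with exact 95% intervals as error bars. Lipid-associated-like cells stand at 24.4% in WT HFD and 14.6% in CKO HFD against 2.84% and 1.42% under normal diet, while the resident-like HFD bars depend on the clustering.

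Marker genes read cell by cell at equal depth over all phagocytes, without a split into classes, gave a lower share for Trem2 in CKO under HFD. The clusters still set which cells counted as phagocytes and as fibroblast-like. This gene, a lipid receptor, was found in 37.1% (35.7 to 38.6) of thinned WT HFD phagocytes, 24.1% (23.1 to 25.2) in CKO HFD, 8.06% (7.06 to 9.14) in WT normal diet and 7.82% (6.91 to 8.81) in CKO normal diet, against 2.00% and 1.72% of fibroblast-like cells of the HFD libraries. Unthinned shares were 74.3%, 34.5%, 15.1% and 15.1%, at median depths of 14530, 3741, 3989 and 3786.5 UMIs for phagocytes and 12833.5, 3318, 2680.5 and 3519.5 for fibroblast-like cells. Folr2, a folate receptor of resident macrophages, was found in 18.4%, 37.1%, 30.4% and 36.8% of thinned phagocytes (40.5%, 45.9%, 41.2% and 48.4% unthinned), with 2.00% and 3.45% in the HFD fibroblast-like cells. Lyve1, a hyaluronan receptor, was found in 6.08%, 14.6%, 15.2% and 22.6% (12.7%, 19.9%, 22.8% and 32.1% unthinned), with 2.00% and 0% in the HFD fibroblast-like cells. In WT and CKO normal diet, 1 of 4 and 2 of 6 fibroblast-like cells had Lyve1, and 0 of 4 and 1 of 6 had Folr2. These are too few cells to give a background under normal diet. Mki67, expressed in dividing cells, was found in 10.9%, 5.74%, 4.76% and 6.22% (22.5%, 8.79%, 8.43% and 10.2% unthinned), and in 0% of fibroblast-like cells. Gpnmb (8.85% and 3.65% in the HFD phagocytes) and Cd9 (16.7% and 13.4%) were below the fibroblast-like cells (8 and 9 of their cells for Gpnmb, 24 and 29 for Cd9), so that these cells give no background for either gene. Timd4, of long-lived resident macrophages, was found in 0.113%, 0.989%, 3.04% and 4.47% of thinned phagocytes (0.691%, 1.57%, 6.65% and 9.35% unthinned) and Ly6c2, of classical monocytes, in 0.630%, 2.52%, 1.43% and 1.03% (1.98%, 3.70%, 2.23% and 1.33% unthinned), each with 0% in fibroblast-like cells.

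The comparison of CKO with WT under HFD asks how the macrophages labelled CKO differ from WT in obese fat. Il10, the anti-inflammatory cytokine, was lower in CKO, at 23.4 against 81.4 CPM, a ratio of 0.288 (0.267 to 0.309). Chemokine and monocyte genes were higher in CKO, with Ccl24, Ccl2 and Ccl12 between 2.78 and 4.65 times the WT level. Lipid-associated macrophage genes such as Atp6v0d2 and Lpl were lower, and resident genes such as Cd163 and Pf4 were higher. These values stand beside differences between the 2 libraries as a whole. The median log2 ratio of all 7812 genes was −0.21, and TMM moved it to −0.03. Among 5 groups of genes by span, the median ran from 0.11 in the shortest (median span 4.74 kb) to −0.64 in the longest (123 kb), with a Spearman rho of −0.588 across genes, which are not independent replicates. List percentiles do not take this trend into account. It was removed, as an alternative, only for the lipid-associated, resident and MHC class II lists.

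Among the 10 highest genes of CKO over WT under HFD, Cxcl13, a chemoattractant of B cells on chromosome 5 (95956951 to 95961068), stood at 50.9 against 1.20 CPM, a ratio of 42.4 (34.2 to 53.2). Its UMIs came from 293 cells, and 10 cells held 30.9% of them. Ccl24, an eosinophil chemoattractant, was 4.65 times (4.51 to 4.80) as high, and 19.1 times (17.8 to 20.5) within lipid-associated-like cells. The latter compares different clusters of WT and CKO, and Ccl24 is a leading gene of the CKO one. The monocyte genes Plac8 (4.76 times) and Ifitm6 (4.48 times) and the antiviral membrane protein gene Ifitm3 (3.23 times) were also higher. Arg1, arginase of alternatively activated macrophages, was at 85.5 against 21.5 CPM, a ratio of 3.97 (3.74 to 4.23). Ccl12 (3.32 times) and Ccl2 (2.78 times), ligands of the monocyte receptor CCR2, stood with the metal-binding metallothionein gene Mt1 (3.03 times) and with Fxyd2, a regulator of the sodium pump (3.15 times). With classes weighted equally, the log2 ratio of Plac8 turned from 2.25 to −0.16. Within classes its ratio was 4.34 in dividing, 17.1 in lipid-associated-like and 2.73 in resident-like cells. All 10 genes kept their direction in each of the 3 classes measured.

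The 10 lowest genes were led by Cmss1 (chromosome 16, 57302000 to 57606864), at 340 CPM in CKO HFD against 3592 CPM in WT HFD, 10.6-fold lower. Cmss1 stood at 887 and 838 CPM in the WT and CKO normal-diet libraries, so that both HFD libraries were far from those. The nuclear RNA Neat1 was 5.82-fold lower, the mitochondrial leucyl-tRNA synthetase gene Lars2 5.44-fold, the Mediator kinase gene Cdk8 5.25-fold, Gphn 4.91-fold, the kinase gene Camk1d 4.70-fold and the Notch coactivator gene Maml3 4.57-fold. Il31ra, a cytokine receptor gene (6.58-fold), Xylt1 (4.10-fold) and the NF-kappaB inhibitor gene Tnip3 (3.23-fold) completed them. In fibroblast-like cells the median log2 ratio of these 10 genes was −2.60, against −2.33 in phagocytes and −2.36 in all cells outside the phagocytes. Gm42418, a predicted gene that overlaps a ribosomal RNA repeat and was chosen after its values were seen, took 4.46% of phagocyte UMIs in WT HFD, 0.699% in CKO HFD, 3.01% in WT normal diet and 3.57% in CKO normal diet. Outside the phagocytes Gm42418 took 4.50%, 0.728%, 2.78% and 3.06%.

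**Figure D2:**
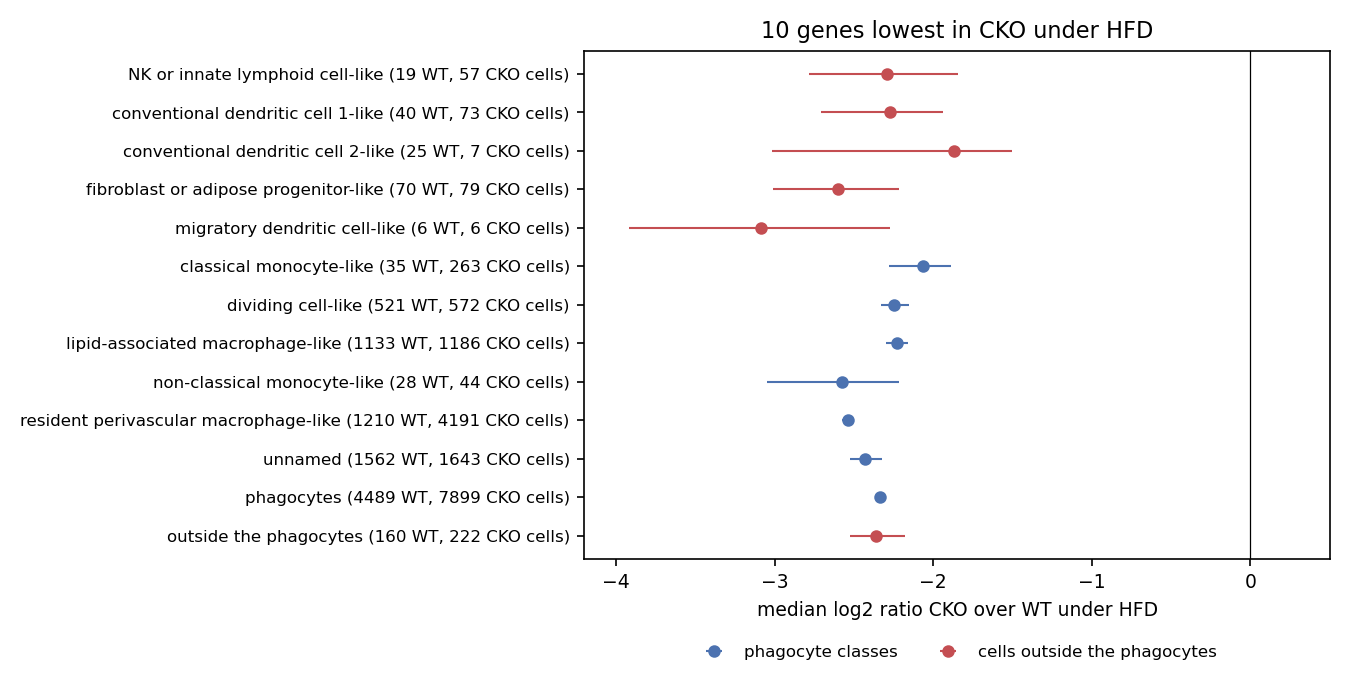
Median log2 ratio of CKO over WT under HFD (horizontal axis) of the 10 genes lowest in CKO, by rebuilt class, with counting intervals as bars. The median is −2.60 in fibroblast-like cells, −2.54 in resident-like, −2.23 in lipid-associated-like and −2.07 in classical monocyte-like cells.

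Lipid-associated genes under HFD had a median log2 ratio of −0.40 (−0.41 to −0.37), or −0.18 relative to all genes, at percentile 0.12 of the random lists, with 8 of 22 members over 1.5 times lower and 1 higher. Atp6v0d2, a subunit of the vacuolar proton pump, had a ratio of 0.299 (0.281 to 0.318), the lipoprotein lipase gene Lpl 0.569, the galectin gene Lgals3 0.706 and Apoe 0.780, while the integrin gene Itgax had 1.73. Lipid handling genes followed at −0.39 (percentile 1.505, 7 of 25 lower), with the lipid-sensing receptor gene Pparg at 0.314, and lysosome genes at −0.26 (percentile 4.16, 8 of 29 lower), with Ctsb at 0.727. Relative to all genes, the lipid handling median was −0.18 and the lysosome median −0.046, so the latter lay near that of all genes. Within lipid-associated-like cells the lipid-associated median was −0.21, against −0.26 for all genes there. Resident genes had a median of 0.59 (0.54 to 0.61; percentile 99.98), 0.80 relative to all genes, with 11 of 21 members higher and 0 lower. Cd163, the haemoglobin scavenger receptor, had a ratio of 2.44 (2.37 to 2.52), Pf4 2.24 and the resistin-like gene Retnla 1.54, but the mannose receptor gene Mrc1 0.784. Within resident-like cells the resident median was 0.07 and within lipid-associated-like cells −0.42. Within dividing cells the lipid-associated median was −0.44 (percentile 0.05, 9 of 22 lower) and the resident median 0.14 (percentile 95.96, 5 of 21 higher). With classes weighted equally, the lipid-associated median was −0.19 and the resident median −0.0032, or 0.033 and 0.22 relative to all genes, so that the lipid-associated list no longer lay below them.

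Monocyte and chemokine genes were higher in CKO HFD. Classical monocyte genes had a median of 1.29 (percentile 100, 8 of 15 higher) with S100a6 at 2.44, while Ccr2 had 0.866. Chemokines had 1.05 (percentile 100, 11 of 18 higher) with Ccl4 at 1.92, and the chemokine median was 0.64 within lipid-associated-like and 0.57 within resident-like cells. Interferon genes stood at 0.36 (percentile 100, 3 of 14 higher and 1 lower) with Cxcl10 at 2.46, and inflammatory genes at 0.32 (percentile 99.9, 2 of 19 higher and 1 lower) but at 0.053 within dividing cells, where over all phagocytes Cxcl2 had 1.34 and the inflammasome gene Nlrp3 0.606. MHC class I genes had 0.26 (percentile 99.8, 1 of 14 higher), with B2m at 1.44. MHC class II genes had 0.21 (percentile 71.3), as H2-Eb1 had 1.39 and Cd74 1.19 while Ciita, their master regulator, had 0.529 (0.506 to 0.553). Alternative activation genes stood at 0.62 (percentile 100), complement at 0.32 (percentile 98.4) with C3 at 3.69, matrix remodelling at 0.22 (percentile 99.6), and iron handling at 0.31 (percentile 98.9).

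Of the metabolic lists under HFD, those of oxidative phosphorylation and hypoxia were higher in CKO. Oxidative phosphorylation genes had a median of 0.44 (percentile 100, 14 of 29 higher), with the respiratory chain genes Cox7a2 at 2.00 and Cox8a at 1.96, and hypoxia genes 0.54 (percentile 100) with Mif at 1.65. Cholesterol synthesis (−0.02), fatty acid synthesis (−0.04), glycolysis (−0.09) and phagocytic receptor genes (−0.09) were near 0 and turned positive under TMM. Cell division genes had −0.37 (percentile 6.92, 9 of 22 lower), with Mki67 at 0.419, and unfolded protein genes −0.33 (percentile 7.10), with the chaperone gene Hspa5 at 0.637. BLIMP1 related genes had 0.06 (percentile 95.3), where Il10 was the lowest and the survival gene Bcl2a1b (1.55) the highest. Beside these lie the measures of quality: the dissociation response list stood at 0.24 (percentile 85.1), the ribosome list at 0.18 (percentile 55.1), free RNA of other cells at 1.18 over 3 members and the sex list at −0.37 over 4. Mitochondrial genes took 2.80% of phagocyte UMIs in WT HFD, 1.85% in CKO HFD, 1.80% in WT normal diet and 1.91% in CKO normal diet, and ribosomal protein genes 15.4%, 20.6%, 13.2% and 12.1%.

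The comparison of CKO with WT under normal diet asks the same of lean fat, between 2 libraries of near equal depth in which the median of all 8094 genes was 0.03 and gene length had little trend (rho 0.0863). Il10 (chromosome 1, 131019845 to 131024974) was the gene with the lowest ratio, at 19.5 CPM in CKO and 55.4 CPM in WT, 0.351 (0.314 to 0.393). The early response genes Egr3 and Egr2, the matrix proteases Mmp9 and Mmp12 and the lipid droplet coat gene Plin2 were also lower in CKO. Resident genes had a median log2 ratio of 0.26, below that of Lyve1 at 0.61. Differences were smaller than under HFD: of the 20 named genes, the farthest on each side were 2.39 times higher and 2.85-fold lower.

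Higher in CKO under normal diet were the stress chaperone genes Hspa1b, at 82.6 against 34.6 CPM (2.39 times, 2.19 to 2.61), and Hspa1a (2.15 times), which also respond to tissue dissociation, and the glucocorticoid-induced gene Fkbp5 (2.10 times). Lyve1 (chromosome 7, 110850607 to 110863239) was at 175 against 115 CPM, 1.52 times (1.45 to 1.61). Rnase4 (1.66 times), the mitotic gene Ube2c (1.64 times), the scavenger receptor gene Colec12 (1.59 times), Tppp3 (1.49 times) and the cyclin gene Ccnd1 (1.45 times) followed. Slpi, a protease inhibitor gene, had a ratio of 2.27, but 10 cells held 77.7% of its UMIs, and its log2 ratio turned from 1.18 to −0.086 with classes weighted equally. Lower in CKO were Egr3 (2.25-fold), Mmp9 (2.32-fold), Mmp12 (2.03-fold, with 48.9% of its WT UMIs in 10 cells), Thbs1 (1.87-fold), the fractalkine receptor gene Cx3cr1 (1.71-fold), Plin2 (1.63-fold), Ccl3 (1.62-fold), Tnfaip2 (1.61-fold) and Egr2 (1.57-fold). Of these 20 genes, 6 of the 10 higher and 6 of the 10 lower kept their direction in each of 3 classes with enough cells.

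Il10 was lower in CKO within each class that could be measured. Under HFD the ratio was 0.175 in dividing cells, 0.224 in lipid-associated-like and 0.430 in resident-like cells, and under normal diet 0.217 in dividing, 0.298 in resident-like and 0.621 in non-classical monocyte-like cells. The Il10 UMIs of WT came from 1403 cells under HFD and 449 under normal diet.

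Lipid-associated genes under normal diet had a median of −0.17 (−0.21 to −0.12; percentile 0.00), with 3 of 22 members lower and 0 higher, and resident genes 0.26 (0.22 to 0.30; percentile 100), with 1 of 23 higher. With classes weighted equally these medians were −0.011 and 0.14. Lgals3 had a ratio of 0.865 and Lpl 0.817, while Igf1, a growth factor gene, had 1.33, Mgl2 1.32 and Retnla 1.302. Chemokines (−0.28) and inflammatory genes (−0.24) both lay at percentile 0.00, with Ccl8 at 0.725, Cxcl2 at 0.878 and Clec4e at 0.607. Lipid handling (−0.18, percentile 0.00), matrix remodelling (−0.12, percentile 0.05), hypoxia (−0.14, percentile 0.07), MHC class II (−0.13, percentile 0.29), BLIMP1 related (−0.08, percentile 0.41) and classical monocyte genes (−0.09, percentile 0.82) were also low in rank. Cell division genes had 0.36 (percentile 100, 1 of 22 higher) with the tubulin regulator gene Stmn1 at 1.34, beside dividing shares of 6.70% in CKO and 4.64% in WT, and −0.049 (percentile 5.445) within dividing cells. Also high in rank were cholesterol synthesis genes at 0.24 (percentile 100) with Hmgcs1 at 1.43, and fatty acid synthesis genes at 0.15 (percentile 98.5). The list of free RNA of other cells had a median of 1.13 over 3 members, set by Ighm (ratio 2.20), of which 1 cell held 2956 of the 7111 UMIs in CKO. The dissociation response list stood at −0.02 (percentile 24.7).

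**Figure D3:**
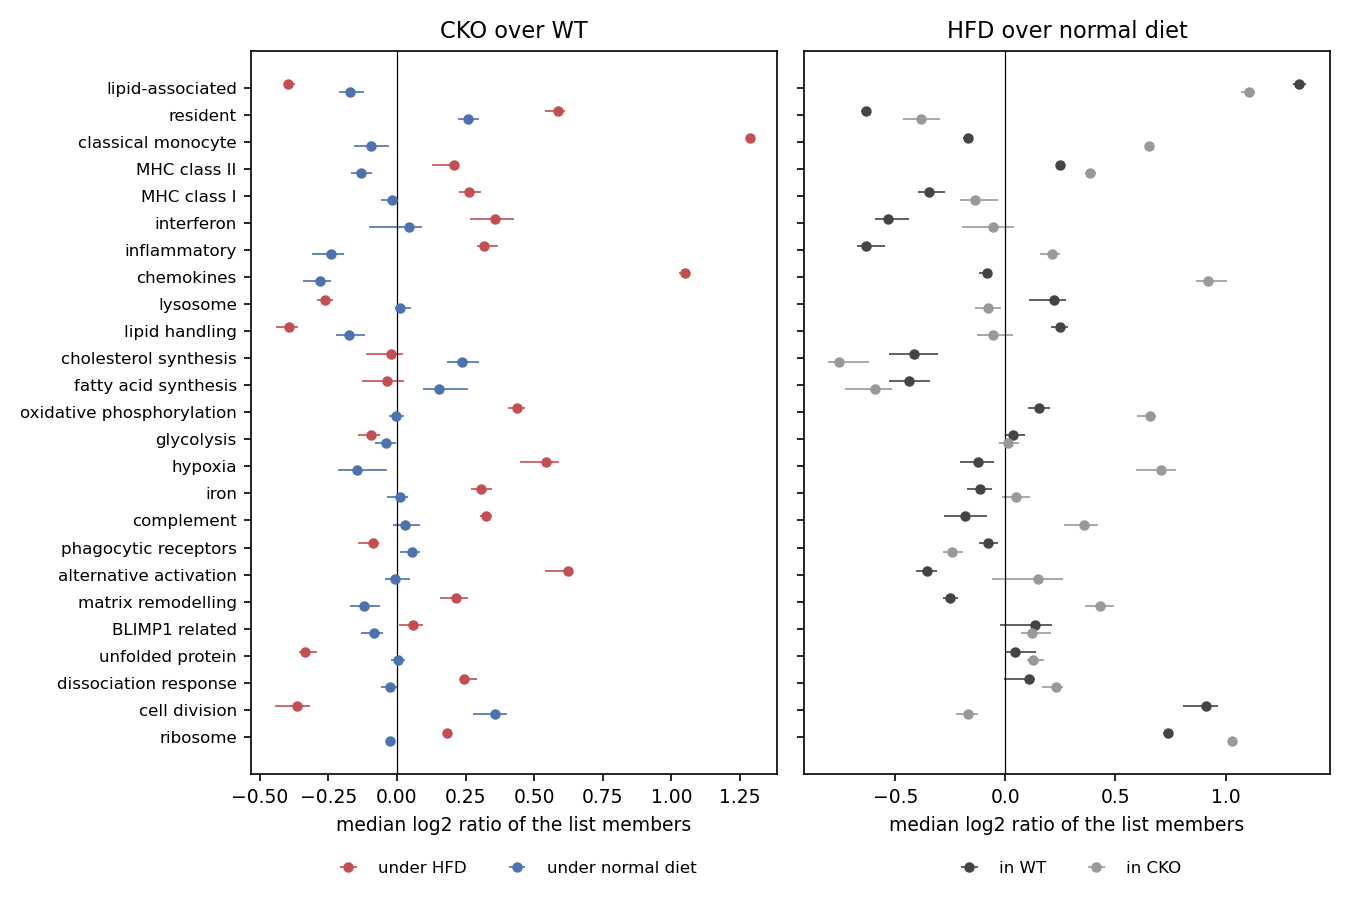
Median log2 ratio (horizontal axis) of 25 gene lists in the phagocytes, CKO over WT on the left and HFD over normal diet on the right, with counting intervals as bars. The lipid-associated list lies at −0.40 and −0.17 on the left and at 1.33 and 1.10 on the right and keeps its directions under TMM, while the medians of glycolysis (−0.09, CKO over WT under HFD) and of the resident list (−0.38, HFD over normal diet in CKO) turn positive.

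The comparison of HFD with normal diet in WT shows the lipid-associated programme of obese fat. Trem2 (chromosome 17, 48346401 to 48354147) stood at 384 CPM under HFD and 51.1 CPM under normal diet, 7.53 times (7.07 to 8.03) as high, and Gpnmb (chromosome 6, 49036546 to 49070929) at 188 against 13.5 CPM, 13.9 times (12.3 to 15.8). Cell division genes were higher as well. Resident, inflammatory and interferon genes were lower. The WT HFD library was the deeper by far, its all-gene median was −0.18, which TMM moved to 0.13, and the longest group of genes had a median of −0.48 against 0.19 in the shortest (rho −0.363 across genes).

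Rnase2a, an eosinophil-associated ribonuclease gene, had the highest ratio in WT, 145 against 3.06 CPM (47.3 times, 36.8 to 61.9). Tmem37 (9.77 times), the replication histone genes Hist1h2ap (8.88 times) and Hist1h1b (6.11 times), Atp6v0d2 (8.81 times), the fatty acid-binding protein gene Fabp5 (4.997 times), Lgals3 (4.09 times) and Cmss1 (4.05 times) were the others, besides Trem2 and Gpnmb. Among the lowest were the integrin gene Itgal (20.5-fold lower), Plac8 (10.997-fold), the lysozyme gene Lyz1 (7.51-fold), Cd24a (9.44-fold), Mmp9 (22.6-fold), the cytokine gene Il6 (18.6 against 152 CPM), Upb1 (12.7-fold), the retinoic acid synthesis gene Aldh1a2 (7.11-fold) and Bhlhe40 (5.61-fold). Saa3, an acute phase gene, stood at 0.442 against 52.5 CPM, with 61.0% of its normal-diet UMIs in 10 cells. All 20 kept their direction in each class measured, except Plac8, which had a ratio of 1.11 in resident-like cells. The size was not always kept: within resident-like cells Lyz1 had a ratio of 0.771 and Itgal 0.234, though Cd24a had 0.083. Lyz1, Cd24a, Il6, Aldh1a2 and Bhlhe40 were leading genes of unnamed clusters 6 and 10. These made up 12.6% and 13.7% of WT normal diet, and 2.88% and 0.258% of WT HFD. Itgal and Plac8 led the larger non-classical monocyte-like cluster (12.5% and 0.581%). The pooled ratios of these genes therefore also carry the shares of these clusters.

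The lipid-associated list in WT had a median of 1.33 (1.305 to 1.365; percentile 100), 1.52 relative to all genes, with 15 of 22 members over 1.5 times higher and 2 lower. Apoe had a ratio of 2.22, Ctsb, of the lysosome list, 1.73 and the fusion gene Dcstamp 0.279. Within resident-like cells the same list stood at 0.74, and with classes weighted equally at 0.63, against −0.21 for all genes in the latter setting. Lysosome (0.22, percentile 98.4) and lipid handling genes (0.25, percentile 99.5) were higher in rank. Cell division genes had 0.91 (percentile 100, 14 of 22 higher) with Mki67 at 2.67 and Stmn1 at 2.27, and ribosome genes 0.74 (percentile 100), while oxidative phosphorylation had 0.15 (percentile 98.4) and MHC class II 0.25 (percentile 85.4) with Ciita at 1.97. Resident genes had −0.63 (percentile 0.05, 12 of 23 lower), inflammatory genes −0.63 (percentile 0.24), interferon genes −0.53 (percentile 1.59) with Cxcl10 at 0.180, and cholesterol synthesis genes −0.42 (percentile 7.17). Igf1, a member of the resident list, went the other way at 3.59. The classical monocyte (−0.17), chemokine (−0.08), hypoxia (−0.13), iron (−0.12), complement (−0.18), phagocytic receptor (−0.08) and matrix remodelling (−0.25) medians turned positive under TMM.

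The comparison of HFD with normal diet in CKO showed the lipid-associated programme too. Trem2 was 5.20 times (4.88 to 5.55) and Gpnmb 8.39 times (7.26 to 9.75) as high under HFD, and the adipocyte-type fatty acid-binding protein gene Fabp4 7.14 times. Chemokine, monocyte, hypoxia and oxidative phosphorylation genes were higher, while their medians in WT were between −0.17 and 0.15. The difference between the genotypes was not tested. This pair had the widest library difference, with an all-gene median of −0.44, moved to 0.08 by TMM, and −1.17 in the longest group of genes against 0.31 in the shortest (rho −0.655 across genes).

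Rnase2a again led, at 148 against 5.34 CPM (27.6 times, 23.1 to 33.4). Arg1 was 9.36 times (8.13 to 10.8) as high, the chitinase-like gene Chil3 7.95 times, the lipid droplet gene Hilpda 6.16 times, the galectin gene Lgals1 4.91 times, Mt1 4.59 times and Ccl2 4.07 times. The 10 lowest were mostly long genes, such as Hdac9 with a span of 869516 bases: the nuclear receptor gene Nr4a3 (11.7-fold lower), the deacetylase gene Hdac9 (8.80-fold), Aff3 (9.94-fold), Chn2 (9.13-fold), the phospholipase gene Plcb1 (7.61-fold), Mpp7 (8.12-fold), Dennd4a (6.53-fold), Lsmem1 (9.33-fold), the calcium channel gene Itpr1 (10.3-fold) and Thsd4 (37.2-fold). All 20 kept their direction in both classes measured.

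The lipid-associated list in CKO had a median of 1.10 (1.07 to 1.14; percentile 100), 1.54 relative to all genes, with 15 of 22 members higher and 1 lower. Lgals3 had a ratio of 3.33, Tyrobp 2.30 and Apoe 1.76. With classes weighted equally the median was 0.087, against −0.48 for all genes in that setting. Within resident-like cells the list median was 0.83. Chemokines had 0.92 (percentile 100, 12 of 18 higher) with Ccl4 at 2.66, classical monocyte genes 0.65 (percentile 99.9), hypoxia genes 0.71 (percentile 99.99) with Mif at 2.87, oxidative phosphorylation genes 0.66 (percentile 99.96) with Sdhb at 2.58, matrix remodelling genes 0.43 (percentile 99.8) and ribosome genes 1.03 (percentile 100). MHC class II genes had 0.39 (percentile 74.2), with Cd74 at 2.05 and H2-DMb2 at 0.177. Cholesterol synthesis genes were lower at −0.76 (percentile 5.04, 10 of 17 lower). The resident median was −0.38 (percentile 11.4) and turned to 0.11 under TMM, so no direction is given for it. Those of MHC class I (−0.14), interferon (−0.06), lysosome (−0.08), lipid handling (−0.06), phagocytic receptors (−0.24), cell division (−0.17) and free RNA (−0.42) turned likewise.

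The difference of the genotype ratios between diets was taken as the log2 ratio under HFD minus that under normal diet, and was not tested. It was −0.23 for the lipid-associated list and 0.33 for the resident list, which had the same direction under both diets. Relative to all genes, the lipid-associated median was −0.18 under HFD and −0.20 under normal diet, so no difference between diets is claimed for that list. The resident median was 0.80 and 0.23 relative to all genes. For alternative activation the difference of the genotype ratios was 0.63 and for oxidative phosphorylation 0.44. The resident median lay above the lipid-associated median by 0.98 under HFD and by 0.43 under normal diet.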

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

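Of the tests weighed here, the comparison with the genotype ratios under normal diet, those on Prdm1 and those on the share of phagocytes with an Igkc UMI and on Igkc without its top cell were chosen only after their results had been seen. Some gene lists drew attention because their genotype ratio pointed one way under HFD and the other way under normal diet; the difference (log2 ratio CKO over WT under HFD minus that under normal diet) was not tested. It was 1.38 for the classical monocyte list, 1.33 for chemokines, 0.69 for hypoxia, 0.56 for inflammatory genes, 0.34 for MHC class II, 0.34 for matrix remodelling, 0.21 for ribosome, 0.14 for BLIMP1 related genes, −0.14 for phagocytic receptors and −0.72 for cell division. The HFD side of each of these rests on the pair of libraries that differ as described next, and under TMM the phagocytic receptor median turned.

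The 10 named genes lower in CKO than in WT under HFD, Cmss1, Neat1, Lars2, Cdk8, Camk1d, Gphn, Il31ra, Maml3, Xylt1 and Tnip3, were low in every class of cells. Outside the phagocytes their median log2 ratio was −2.36 (−2.53 to −2.18), as a difference between the libraries that acts on every cell type predicts. Removing the trend over gene length left −1.60 (−1.62 to −1.56). The genes were picked as the lowest of this same comparison and so lie below that trend by choice, and this value cannot decide on length. Under normal diet the 10 genes stood at −0.025 (−0.048 to 0.018), which argues against a genotype effect of like size under both diets. A difference in handling or preparation of the CKO HFD or WT HFD library may underlie the pattern, and Gm42418 at 0.699% and 4.46% of phagocyte UMIs lies in the same direction. A genotype effect that appears only under HFD and acts on every cell type stays open, as library and group are the same.

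Prdm1 was not lower in CKO than in WT. A swap of the genotype labels would make Prdm1 lower in the libraries labelled WT than in those labelled CKO if the tag is lost with the deletion; the ratios CKO over WT were 1.06 (0.972 to 1.15) under HFD and 1.21 (1.07 to 1.37) under normal diet, and the highest ratios within a phagocyte class 1.42 (1.23 to 1.64), in lipid-associated-like cells, and 2.81 (1.58 to 5.20), in classical monocyte-like cells. The HFD pair does not show the loss a swap would need. A swap under normal diet cannot be told apart from correct labels, since the ratio over all phagocytes is small and those within classes run from 0.962 to 2.81. Over the 4 libraries together, Prdm1 stood at 0.914 CPM (0.0231 to 5.09) in fibroblast-like cells, against 22.3 to 27.9 CPM in the phagocytes. Most of these cells came from the HFD libraries, where Prdm1 stood at 1.28 CPM (0.0325 to 7.15) in WT and 0 CPM (up to 14.8) in CKO. This argues against free RNA under HFD. The 4 and 8 fibroblast-like cells of WT and CKO normal diet allow up to 263 and 70.8 CPM. They cannot decide on free RNA under normal diet. What also stays open is that the 3′ tag may lie outside the deleted part, so that transcripts of the deleted allele are still counted. This would also leave a swap open. The deletion may instead be partial in these phagocytes. Il10, of the list of BLIMP1 related genes, was lower in both CKO libraries. That list holds genes described elsewhere as bound or repressed by BLIMP1. Loss of repression would raise a gene, but the list does not say in which direction BLIMP1 acts on each bound gene. The list medians were 0.06 under HFD and −0.08 under normal diet. Il10 therefore does not decide whether BLIMP1 was lost.

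Igkc, an immunoglobulin gene, was higher in the summed UMIs of the phagocytes of both CKO libraries, 224 times (170.1 to 301.2) under HFD and 47.2 times (36.5 to 62.2) under normal diet, although the sort for CD45, CD11b and CD64 and against a lineage stain should leave out B and plasma cells. A few B or plasma cells among the phagocytes are a candidate explanation: 99.8% of the Igkc UMIs of the CKO phagocytes lay in cells with at least 10 of them, and 1 cell held 5578 of 5594 in CKO HFD. Without the top cell of each library, the ratio was 0.797 (0.418 to 1.45) under HFD, so that the difference there rests on 1 cell, and 21.9 (15.3 to 32.5) under normal diet. The latter ratio also rests on few cells, as only 7 phagocytes of CKO normal diet had an Igkc UMI. Its interval takes UMIs as independent and is too narrow for UMIs held by so few cells. Free RNA of B or plasma cells and transcription across the phagocytes are both argued against by the cells with an Igkc UMI, 0.139% (0.0695 to 0.249) of the phagocytes in CKO HFD and 0.176% (0.0707 to 0.362) in CKO normal diet, where the same UMIs spread in proportion to depth would reach 46.6% and 45.8%. In WT these cells were no fewer, 0.913% (0.656 to 1.24) under HFD, at a median depth of 14530 UMIs against 3741 in CKO HFD, and 0.238% (0.103 to 0.468) under normal diet. The tests planned for these 2 did not decide: the other B or plasma cell markers had median ratios of 2.86 under HFD and 1.01 under normal diet, and Igkc in phagocytes stood at 0.0328 times (0.0315 to 0.0341) its level outside them in CKO HFD and 5.21 times (3.93 to 7.06) in CKO normal diet. The median joins markers that differed. Jchain, a plasma cell gene, had 387 UMIs in CKO against 6 in WT under HFD (132 times, 60.0 to 361). Under normal diet it had 98 against 3 (28.7 times, 9.55 to 142). The B cell gene Cd79b had ratios of 0.603 and 0.923 under HFD and normal diet, and Ms4a1 0.511 and 0.362. Which cells hold the Jchain UMIs is not given here. Transcription in single phagocytes, or B or plasma cells joined to a phagocyte in 1 droplet, stays open.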

How the results depend on the processing

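The alternatives for the list medians of HFD over normal diet in CKO, those for the resident-like shares, and the settings named as added were chosen after seeing the data; the others were planned. The values given are those that moved beyond their counting interval or turned; the cause was not tested. Comparisons stand in the order CKO over WT under HFD, CKO over WT under normal diet, HFD over normal diet in WT and in CKO, with reported medians of −0.40, −0.17, 1.33 and 1.10 for the lipid-associated list, 0.59, 0.26, −0.63 and −0.38 for the resident list and 0.21, −0.13, 0.25 and 0.39 for MHC class II. Of the medians of these 3 lists and the shares of the lipid-associated-like and resident-like classes, 150 values kept their direction within the counting interval, 112 moved and 2 medians turned. These counts take each share by itself. Between libraries, the order of the lipid-associated-like shares never turned, and that of the resident-like shares turned under 2, 0, 1 and 2 of 11 settings. Other lists also turned under TMM, and those reported are named with the comparisons. The lipid-associated list kept its sign in all 4 comparisons under every setting run. Relative to all genes, a reading chosen after seeing the data, it turned from −0.18 to 0.033 under HFD with classes weighted equally, and the resident list in CKO turned under 5 of 15 settings. No paired analysis was possible because the labels give no number that links animals across the libraries. No replicates limit every result to these libraries.

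TMM scaling: lipid-associated −0.21 under HFD, 1.63 in WT, 1.60 in CKO; resident 0.72, −0.34 and 0.11, the last reversed; MHC class II 0.39, 0.73 and 0.88. Totals without mitochondrial and ribosomal protein genes: lipid-associated −0.32, 1.39 and 1.25; resident −0.58 in WT and −0.24 in CKO; MHC class II 0.28, 0.30 and 0.51.

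A minimum of 50 CPM gave lipid-associated −0.37 and −0.11 for the genotypes and 1.01 for diet in CKO, resident 0.47, −0.56 and −0.23 (HFD, WT, CKO), and MHC class II 0.44 in WT. No minimum gave resident 0.53 and −0.66 and MHC class II 0.23, 0.047 and 0.26. A pseudocount of 10 gave lipid-associated −0.36, 1.28 and 0.99.

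Cells weighted equally gave lipid-associated −0.43, 1.19 and 0.97, resident 0.68, −0.90 and −0.47, and MHC class II 0.43 in WT and 0.55 in CKO. Thinned cells gave lipid-associated −0.42, 1.21 and 0.89, resident 0.68 and −0.79, and MHC class II −0.19 under normal diet, 0.31 in WT and 0.46 in CKO. All kept cells gave lipid-associated 1.38 and 1.15 for diet, resident −0.55 in WT, and MHC class II 0.20 and 0.31.

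Classes weighted equally gave lipid-associated −0.19, −0.011, 0.63 and 0.087; resident −0.0032 under HFD (reversed), 0.14, −0.76 and −0.85; MHC class II 0.52 in CKO. Of the named genes, Plac8 turned to −0.16 under HFD and Slpi to −0.086 under normal diet; 19 of 20 kept their direction in each genotype comparison, and 20 of 20 in each comparison under the other 6 settings run on genes. Equal class weights moved 4, 1, 12 and 5 of the 20 by over 1.5 times in the 4 comparisons, and cells weighted equally 1, 0, 2 and 2. Of the genes named from the lists, 11 of 102, 4 of 106, 11 of 102 and 15 of 104 turned under TMM, and 13, 18, 7 and 7 with classes weighted equally.

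With doublet calls kept, the lipid-associated median was −0.42 under HFD, the resident −0.47 and MHC class II 0.34 for diet in CKO; the lipid-associated-like share of CKO HFD was 12.2%, and the resident-like shares 11.2% in WT HFD, 27.8% in WT normal diet and 34.3% in CKO normal diet. Applying the doublet rule to all 4 libraries (added) moved no value, but it removed 3.72%, 6.99%, 2.97% and 3.44% of the cells of WT HFD, CKO HFD, WT and CKO normal diet, so the shares stayed unequal.

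Removing the gene length trend (added) gave lipid-associated −0.21 under normal diet, 1.37 in WT and 1.02 in CKO, resident −0.47 in CKO, and MHC class II 0.27, 0.11 and 0.76 (HFD, WT, CKO). Without the mixed clusters 10 and 21 (added), lipid-associated was −0.25 under normal diet and 1.07 in CKO, resident 0.34 under normal diet and −0.59 in WT, MHC class II 0.45 in WT, and the resident-like shares 39.6% and 47.4% under normal diet. Without the shallow clusters 12 and 15 (added), resident was −0.61 in WT. Without the top Igkc cell of each library (added), the log2 ratio of Igkc was −0.33 under HFD, reversed from 7.81, and 4.45 under normal diet.

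Shares moved with the clustering. Leiden 0.5 gave 3.04% lipid-associated-like in CKO HFD, and 1.25%, 30.1% and 37.6% resident-like in WT HFD, WT normal diet and CKO normal diet. Leiden 2 gave 10.3% lipid-associated-like in CKO HFD and 35.7%, 23.8% and 31.7% resident-like in CKO HFD, WT and CKO normal diet. Clustering of thinned cells gave 12.4% lipid-associated-like in CKO HFD and 10.7%, 30.7% and 37.0% resident-like in WT HFD, WT and CKO normal diet. Leaving out class markers (added) gave 21.8% lipid-associated-like in WT HFD and 1.16%, 49.99%, 29.2% and 36.2% resident-like in WT HFD, CKO HFD, WT and CKO normal diet. Centring within libraries (added) gave 11.2%, 4.67% and 3.02% lipid-associated-like in CKO HFD, WT and CKO normal diet, and 13.1%, 12.02%, 19.6% and 22.6% resident-like, which turned CKO over WT under HFD to 0.919 and HFD over normal diet in CKO to 0.531; Leiden 2 turned HFD over normal diet in WT to 1.088. As a share of phagocytes, resident-like cells were 53.1%, 37.3% and 44.8% in CKO HFD, WT and CKO normal diet; without cluster 0 (added) 14.99% in CKO HFD, which turned CKO over WT under HFD to 0.589 and HFD over normal diet in CKO to 0.363; under the stricter filter 32.2% and 39.96% under normal diet. Lipid-associated-like shares were lower in CKO than in WT, and higher under HFD than under normal diet, under all clusterings run.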

Other observations

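The values of this part were chosen after they had been seen and were not tested. Within resident-like cells the MHC class II list was higher under HFD than under normal diet in both genotypes, with medians of 0.62 (0.58 to 0.66; percentile 97.1) in WT and 1.16 (1.10 to 1.21; percentile 99.1) in CKO, and the resident list was lower, at −0.71 and −0.74, against −0.24 and −0.52 for all genes there. Oxidative phosphorylation genes, which make up the respiratory chain, were higher within the same class at 0.52 in WT and 0.84 in CKO. Which HFD cells fall in this class depends on the clustering. In CKO over WT under normal diet, chemokine genes stood at −0.53 (−0.60 to −0.28) within resident-like cells, with 7 of 17 members over 1.5 times lower, against −0.09 within non-classical monocyte-like cells. Plin2, which coats lipid droplets, had a ratio of 0.557 (0.514 to 0.604) in the resident-like cells of CKO over WT under normal diet and 0.671 (0.650 to 0.693) in those under HFD.

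Prdm1 differed between classes within a library. In classical monocyte-like, lipid-associated-like, resident-like and dividing cells it stood at 38.4, 29.6, 17.8 and 17.5 CPM in WT HFD and at 41.8, 42.02, 16.7 and 15.4 CPM in CKO HFD. In the same classes it stood at 66.7 (39.5 to 105.4), 47.2 (33.2 to 65.1), 38.3 and 10.8 CPM in WT normal diet and at 188 (135 to 255), 96.9 (68.9 to 132), 36.8 and 15.2 CPM in CKO normal diet. The ratio of CKO over WT under normal diet was 2.81 (1.58 to 5.20) in classical monocyte-like and 2.05 (1.27 to 3.31) in lipid-associated-like cells. Prdm1 was found at 0 UMIs in the type 1 conventional dendritic cell-like cells of WT HFD, which allows up to 6.09 CPM.

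Xist, expressed from the inactive X chromosome of females, stood at 0.0672, 0.0550, 0 and 0.0817 CPM in WT HFD, CKO HFD, WT normal diet and CKO normal diet, and the Y-linked gene Ddx3y at 63.5, 49.8, 130 and 117 CPM. AY036118, a second gene annotated over ribosomal RNA, took 0.141%, 0.0441%, 0.159% and 0.151% of phagocyte UMIs in the same order. In CKO normal diet 1 cell held 2396 of the 3168 Igkc UMIs of the phagocytes.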
